A study of Drosophila melanogaster with 4 samples.

How the data were processed

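RNA from 4 fractions of S2-DRSC cells, 1 library each, was made into TruSeq libraries, per the labels' protocols. The submitters' processing notes name TopHat, Cufflinks and the genome build dm3. Their versions and settings are not given in the sources used here. Per the file headers, the authors deposited 1 table with an FPKM value, its interval bounds and a status for each library.

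The number of libraries in the table whose name matched no sample's labels was 4 of 4, so none of their FPKM values was used for a result. The order of the columns and the values in them were not used to assign fractions. The planned ratios between fractions, gene list medians, correlations across genes and named genes, fixed before the data were examined, were therefore not computed, nor were their alternatives. The depth of the libraries was not analysed here.

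All columns were inspected for their unit and range, over the table as a whole and in a few example rows. In each library most lower interval bounds were 0, and a few rows had a status other than OK. The results reported here were computed only from the row identifier, gene symbol and locus, with Python 3.11.15 and pandas 2.3.3. Symbols were matched, with case, to the symbols and synonyms of gene tables for the Release 6 assembly. A gene annotation of that assembly served to compare gene lengths, and no coordinate was taken from it. Over 6656 loci with 1 row and a symbol in that annotation, the annotated gene length equalled end minus start for 1175 and end minus start plus 1 for 108, while the others had other lengths. Starts were therefore taken to count from 0 and are given after adding 1. A locus is the whole region the table assigns to a row. A total of 4721 rows shared a locus with another row, up to 18 on the same locus. Each of 32 gene lists, also fixed beforehand, was matched by exact symbol or by symbol pattern. Some members were listed with alternative names, and a match to any of these counted as exact. Counts by exact symbol therefore depend in part on which alternative names were listed. A gene that the table names only in a row joining several symbols counts as not found by exact symbol, and 269 rows join symbols. Members not found were then sought under the synonyms in the gene table and in the joined rows.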

Results

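RNA from subcellular fractions of S2-DRSC cells was sequenced. These cells are a Drosophila melanogaster culture line described by the depositors as macrophage-like. There were 4 samples, 1 each from the rough microsome, cytoplasm, naked microsome and stripped ribosome fractions. Rough microsomes are vesicles of endoplasmic reticulum (ER) membrane that carry ribosomes. The naked microsomes and the stripped ribosomes were both prepared from rough microsomes, by releasing the ribosomes with EDTA and puromycin at high salt. By its title, the series asks which transcripts stay with microsomes without ribosomes. The design implies a comparison of rough microsomes with cytoplasm, and one of naked microsomes with stripped ribosomes.

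No expression level and no comparison between fractions is reported here, because the 4 libraries in the deposited table could not be assigned to the 4 fractions. The table calls its libraries P10, S10, ER and free, and the sample labels use none of these names. In one reading of the protocol, ER and free are the rough microsome and cytoplasm, and P10 and S10 are the naked microsome and stripped ribosome. In another, P10 and S10 are the rough microsome and cytoplasm, and ER and free are the naked microsome and stripped ribosome. Only this second reading pairs the columns and the samples in their listed order, but order was not used to decide. These readings exchange both implied comparisons, and nothing in the labels decides between them. Which genes are higher in both comparisons, and how the ratios correlate, would not change with that exchange. Those results were still not computed, since nothing in the labels shows that these readings are the only ones. The full text of the submitters' processing notes was not among the sources used here, so it was not searched for the library names. With 1 library per fraction there would also be no replicate error for any difference. What follows describes only which genes the table lists, and a listed gene was not shown to have RNA in any fraction.

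The table listed 13747 rows with 13641 different gene symbols. Chromosome arm 3R held 3333 rows (24.2%), 2R held 2737, 3L held 2689, 2L held 2535 and the X chromosome held 2182. Of the symbols, 10089 are current names in the fly gene tables used here, 3218 are listed there only as synonyms, and 334 matched neither. Joined symbols were compared whole and not split. A joined symbol could not match the name of a single gene. The symbols of the 269 rows that join symbols are therefore counted among the unmatched, even where they name known genes.

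The gene lists held 384 named members, of which 340 were found by exact symbol and 383 once synonyms and rows joining several symbols were counted. A synonym can belong to more than 1 gene, so the wider matches are less certain. The same row can count for more than 1 member, and a gene on several lists counts on each. By exact symbol, 29 of 32 secreted and matrix proteins, 35 of 38 plasma membrane receptors and adhesion proteins, 12 of 13 genes of the ER translocon and signal peptide machinery, and 14 of 15 ER chaperones and folding enzymes were found. The exact symbol was found for 4 of 7 oligosaccharyltransferase subunits, 8 of 13 lysosomal proteins, 9 of 14 mitochondrial carriers and outer membrane proteins, 6 of 11 membrane subunits and 9 of 9 cytosolic subunits of the V-ATPase proton pump. With synonyms and joined rows, every named member of these 9 lists was found. The 1 member of any list that neither search found was sotv, a heparan sulphate synthesis gene on the Golgi list.

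All 12 glycolytic enzymes, 14 cytoskeletal genes, 22 RNA silencing and mRNA decay genes and 6 protein subunits of the signal recognition particle that were sought were found by exact symbol. So were all 15 markers of other cell types, so a match shows only that the table lists a gene. Symbols of cytosolic ribosomal proteins numbered 79, in addition to sta, and those of mitochondrial ribosomal proteins numbered 70. The symbol pattern for mitochondrially encoded mRNAs matched 0 rows, and no row of the table was placed on a mitochondrial chromosome. Small nuclear and nucleolar RNAs accounted for 257 symbols, of which 6 occurred in several rows. Replication-dependent histones accounted for 25 symbols, of which 6 also occurred in several rows.

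Several reference genes for the secretory pathway lay on a locus of their own, in dm3 coordinates. Xbp1, which encodes a transcription factor of the unfolded protein response, was on chromosome 2R from 17031050 to 17033255. Hsc70-3, the ER chaperone BiP, was on chromosome X from 11695729 to 11701212. Sec61alpha, the channel subunit of the translocon, was on 2L from 6477182 to 6480489. The collagen gene Cg25C was on 2L from 5029615 to 5037114. Among genes for cytosolic proteins, Act5C, an actin, was on X from 5794897 to 5798823, and RpL32, a ribosomal protein, was on 3R from 25870951 to 25871880.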

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

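The minimum locus of 300 bp was among the entry rules fixed beforehand, while the alternatives to it in this part were chosen after seeing the data. All of them bear only on which rows could enter an analysis, not on any expression result. On a locus of at least 300 bp there were 13634 rows. Without that minimum there were 13747, and leaving out repeated or joined symbols there were 13263. Leaving out rows that share a locus with another row gave 8913. A row that joins several symbols stays in under this rule if no other row has the same locus. No paired analysis was possible because each fraction has 1 library and no library was assigned to a fraction. The other settings chosen beforehand for the comparisons, such as other pseudocounts and scalings, were not run.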
